A study of Rattus norvegicus with 3 samples.

How the data were processed

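Total RNA from 3 samples of cultured rat Schwann cell precursors was hybridized to single-colour 3D-Gene oligonucleotide arrays, with 1 array per sample. Per the labels' protocols, RNA was extracted with ISOGEN and an RNeasy column, amplified as amino allyl aRNA and coupled to Cy5. All 3 samples carry the same labels and form a single group, so the design holds no comparison between conditions. The labels name Schwann cell precursors as the cell type, while the text of the treatment protocol names oligodendrocyte precursors. Nothing in the labels states whether the samples came from separate cultures or animals, so the spread between them may be technical. A p-value here only compares the spread of a gene over these samples with that of other genes of its level.

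The scanner files give, per the file headers, the median intensity of each spot and the median of its local background on a linear scale, with no background subtracted, together with a pass or fail flag at each of several scanner gains and the straight-line fits between those gains. They carry no saturation flag. Each array held 27456 spots, of which 20174 were gene probes, each with its own Ensembl rat gene identifier. The remaining spots were labelled blank, no probe, quality control probe, negative control or positive control. The software and version behind the intensities are not given in the sources used here. The deposited value table holds normalized intensity on a linear scale. Set against the scanner files, each of its columns was a straight line of the spot median, with residuals of at most 5.2e-06. The authors' values therefore equal the spot median minus a constant (55.4, 56.9 and 63.8 for replicates 1, 2 and 3) times a factor per array that puts the median of the listed probes at 25. Scale, centring and direction of the table are thus known from the values.

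A gene probe was called above background when its spot median exceeded the mean plus 2 SD of the array's blank spots, after the highest and lowest 5% of them were left out, and when no gain was flagged as failed. The flag removed 3 gene probes on replicate 1, none on replicate 2 and 1 on replicate 3. This rule gave the same calls as the probes listed in the deposited table on replicates 2 and 3. On replicate 1 the table listed 9 further probes at the edge of the threshold.

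For values, spot medians of all spots were corrected with limma's normexp method with an offset of 50, gene probes were quantile normalized across the 3 arrays, and log2 was taken. Local background was not used in the main setting because it followed the spot signal. This choice was made after seeing the data, and normexp with the local background was run as an alternative. The offset reduces the differences of dim probes. Variation was measured on gene probes above background on all 3 arrays. Genes whose variance exceeded that of genes of their level were sought with limma, using an intercept-only fit and the tail p-value of the robust, level-dependent prior for the residual variance, adjusted by Benjamini-Hochberg at 0.05. Genes were also counted whose highest and lowest array differed by at least 1 on the log2 scale. The array farthest from the middle array of each such gene was recorded. Tools were R 4.3.3, limma 3.58.1, Python 3.11.15 and matplotlib 3.10.9.

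The measures were tested on simulated arrays of 16226 genes with the observed levels and with noise that depended only on level. Of 100 genes raised 2-fold on 1 array, 60% had a 2-fold range and 81% passed the variance test. Of 100 genes raised 4-fold, 100% passed each. Among 16026 unchanged genes, 0.087% had a 2-fold range and 3 passed the variance test. These shares hold for noise that is equal among genes of a level and among arrays. They need not hold for the measured arrays, where 1 of the 101 genes with a 2-fold range passed the variance test.

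The background threshold, detection rule, measures and part of the alternatives were fixed before the data were examined. So were 23 gene lists with 299 members (glial, neuronal, mesenchymal and other cell types, signalling, stress and metabolic genes, and control lists). Not planned were thresholds from no probe spots, negative controls or positions blank on all arrays, block medians, cyclic loess and normexp with local background. Leaving out an array was not planned for the counts above background or the variance test. The arrays name probes only by Ensembl identifier. The gene table used here held no Ensembl identifiers, so 0 of the 20174 identifiers matched and no list could be placed on the array. The planned tests of list detection, of Schwann against oligodendrocyte genes and of list shifts per array were therefore not run. The rule for named genes would take the 10 genes of widest range and the 5 largest differences in each direction per array. Without symbols, only the 2 largest differences upward and the 2 largest downward are given, by identifier. Alternatives covered the threshold, the spots it is taken from, background correction, normalization, the filter on dim probes, position on the array, the deposited table and leaving out each array. The number of arrays limits the precision of every value.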

Results

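Gene expression was profiled in 3 samples of rat Schwann cell precursors, the embryonic glial precursors of peripheral nerve that descend from neural crest, grown in modified Sato medium under conditions the labels call normal. The arrays measured 20174 genes, each with a single probe. The samples form 1 group, and the questions the data can answer are which probes gave signal in these cells and how closely the samples resembled each other. Probes carry Ensembl gene identifiers only, so the genes are described here by signal class and by identifier, without symbols.

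Most of the gene probes gave signal above blank spots in all samples. Of 20174 gene probes, 16226 (80.4%) were above background on all 3 arrays, 1104 on 2 arrays, 1248 on 1 array and 1596 (7.91%) on none. Per array, 17200 gene probes (85.3%) were above background in replicate 1, 17990 (89.2%) in replicate 2 and 16944 (84.0%) in replicate 3. Blank spots had a trimmed mean intensity of 55.4 ± 0.738 (SD after trimming) in replicate 1, 56.9 ± 0.594 in replicate 2 and 63.8 ± 0.773 in replicate 3. Before trimming, the SD was 1.77 over 1344 spots, 0.852 over 5808 spots and 1.33 over 1344 spots. Replicate 2's blank spots include 4464 positions that the other arrays label no probe. Its count, and its calls on a single array, therefore rest on another set of blank positions than those of replicates 1 and 3. With the threshold from positions blank on all arrays, 16261 gene probes were above background on all 3 arrays.

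Signal above blank was modest for much of the transcriptome. Among gene probes above background, the median intensity over the blank mean was 53.6 in replicate 1, 38.1 in replicate 2 and 41.1 in replicate 3, and the upper quartiles were 277, 224 and 203. In replicate 1, 50.6% of the probes above background lay below 2 times the blank mean, against 55.7% in replicate 2 and 56.6% in replicate 3. The brightest probe exceeded the blank mean by 56375 units in replicate 1, 46481 in replicate 2 and 57397 in replicate 3. The 100 brightest gene probes carried 23.3%, 24.8% and 24.3% of the signal above blank in replicates 1, 2 and 3, and 74 of them were among the 100 brightest on all 3 arrays.

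Probes called on a single array were close to the threshold. In replicate 2, 769 probes were above background only there, and their median intensity was 1.72 units over the blank mean, with a maximum of 14.5. The corresponding numbers were 233 probes with a median of 2.04 units in replicate 1 and 246 probes with a median of 2.12 units in replicate 3.

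The threshold also admitted spots that hold no gene probe. Of the spots labelled no probe, 43.7% exceeded it in replicate 1, 41.0% in replicate 2 and 32.1% in replicate 3. Of the 96 negative control spots per array, 76.0%, 89.6% and 52.1% exceeded it. These are 24 copies of each of 4 controls that differed widely: all copies of negative control 1 passed on every array, while negative control 2 passed in 33.3%, 62.5% and 12.5%. With the threshold taken instead from the 4 negative controls pooled, a setting chosen after seeing the data, 13058 gene probes were above background on all 3 arrays. The gene probes lying between the blank and the negative control thresholds numbered 3519 in replicate 1, 4588 in replicate 2 and 2936 in replicate 3.

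**Figure D1:**
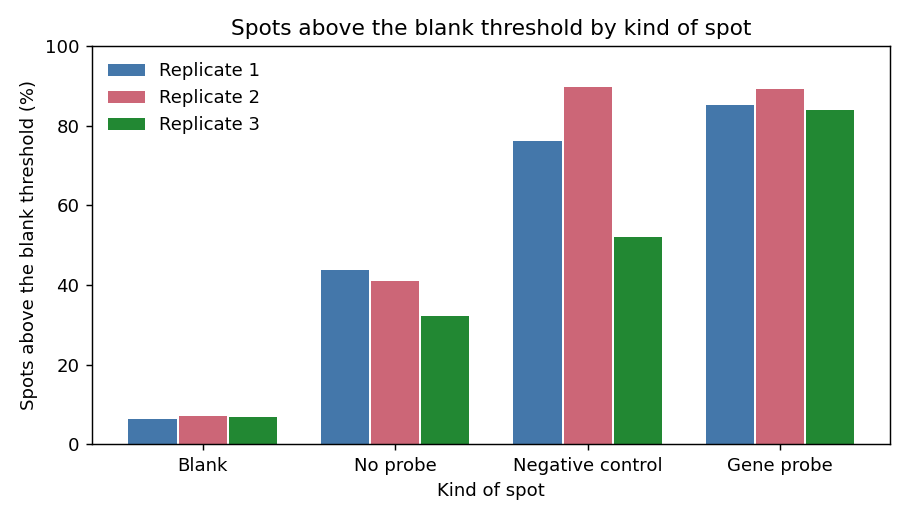
Bars give the percentage of spots (vertical axis) above the blank threshold for each kind of spot (horizontal axis), with 1 bar per replicate and no error bars. Gene probes reach 84.0% to 89.2%, while spots labelled no probe reach 32.1% to 43.7%.

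The 3 samples had closely similar profiles across genes. Over the 16226 gene probes above background on all arrays, Pearson's r of log2 intensity was 0.996 between replicates 1 and 3, 0.989 between replicates 1 and 2 and 0.988 between replicates 2 and 3, and Spearman's rho was 0.993, 0.986 and 0.984. These correlations are across genes, which are not independent replicates. None of the 20174 gene probes had exactly the same spot intensity on any pair of arrays. The median SD of a gene over the 3 samples was 0.093 on the log2 scale, and 90% of genes had an SD of at most 0.27. The median SD was 0.24 with the blank mean subtracted and no offset, 0.30 in the deposited value table and 0.15 with normexp on the local background.

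The relation of variation to level turned between the main setting and values with the blank mean subtracted and no offset. Background correction and the offset, which compresses dim probes, changed together there. The turn therefore cannot be put down to the offset alone. In the main setting, in the lowest quartile of genes by mean level the median SD was 0.027 and no gene had a 2-fold range. In the highest quartile the median SD was 0.18, and 72 of 4057 genes (1.77%) had a 2-fold range. With the blank mean subtracted and no offset, the median SD was 0.20 in the 8113 brighter genes, of which 300 had a 2-fold range, and 0.29 in the 8113 dimmer genes, of which 1175 did. The 24 spots of positive control 1 within an array had a log2 SD of 0.11 in replicate 1, 0.085 in replicate 2 and 0.12 in replicate 3. Those of positive control 2 had 0.18, 0.099 and 0.21. These are raw intensities of control spots within an array, brighter than most genes, and do not measure the spread between samples.

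In the main setting, a 2-fold or wider range between samples was seen for 101 genes (0.622%), and no gene reached 4-fold. The offset shrinks differences of dim probes, and genes reaching 4-fold were not counted in other settings. The absence of 4-fold genes therefore holds for the main setting only. Simulated arrays with noise that depended only on level gave 0.087% of unchanged genes. Their noise did not differ among genes of a level or among arrays, so this share is no null rate for the observed count. Replicate 2 was the array farthest from the middle one for 88 of the 101 genes, above the others for 41 and below for 47. Replicate 1 was farthest for 5 and replicate 3 for 8. Over all 16226 genes the shares were more even, with replicate 2 farthest for 48.4%, replicate 1 for 24.3% and replicate 3 for 27.3%. Without replicate 2, 4 genes differed by 2-fold, against 73 without replicate 1 and 52 without replicate 3. With the blank mean subtracted and no offset, the count was 1475 genes, with replicate 2 farthest for 61.3%. In the deposited value table, which differs in both background treatment and scaling, it was 2647 genes, with replicate 2 farthest for 74.4%. With normexp on the local background, a setting added after seeing the data, it was 2075 genes, and replicate 1 was farthest for 50.4% and replicate 2 for 25.5%.

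The largest differences from the mean of the other samples were all in replicate 2. ENSRNOG00000038402 was 1.51 higher there on the log2 scale (mean 7.38 ± 0.88, SD, n = 3), with spot intensities of 142, 340 and 113 in replicates 1, 2 and 3. ENSRNOG00000026292 was 1.43 higher (mean 9.23 ± 0.83, SD, n = 3), with intensities of 487, 1247 and 385. ENSRNOG00000022857 had a difference of -1.40 (mean 7.55 ± 0.81, SD, n = 3), with intensities of 280, 102 and 248. ENSRNOG00000015496 had a difference of -1.29 (mean 11.17 ± 0.78, SD, n = 3), with intensities of 2865, 1357 and 2971. None of the 4 passed limma's variance test after Benjamini-Hochberg adjustment, with adjusted p-values of 0.072, 0.25, 0.097 and 0.39 in the same order.

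**Figure D2:**
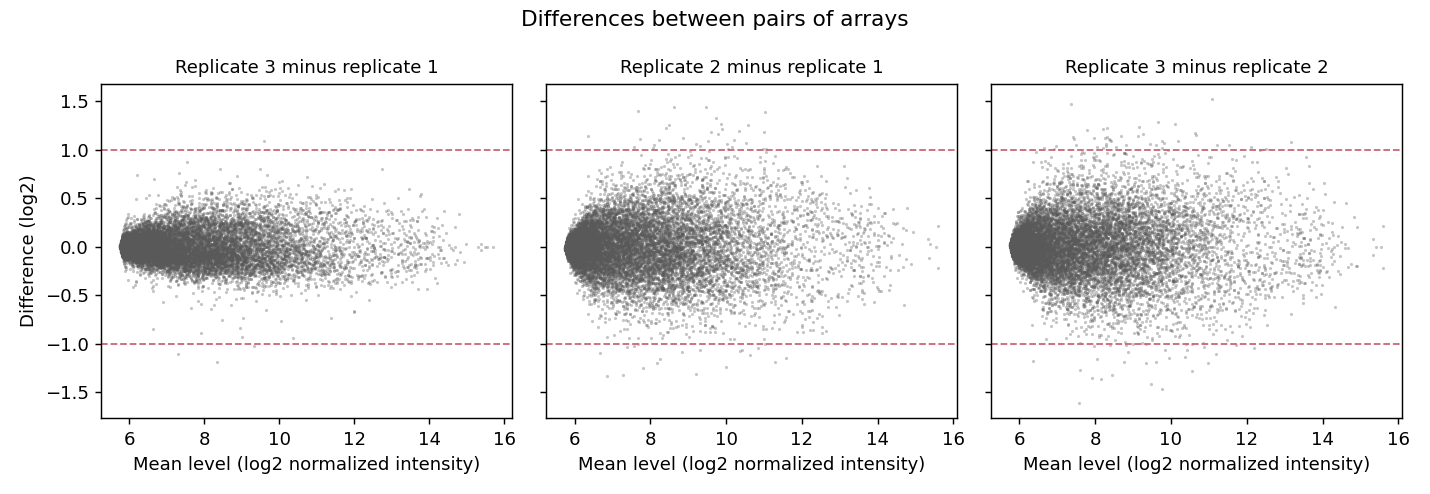
Each point is a gene probe above background on all 3 arrays, with its mean log2 normalized intensity on the horizontal axis and the log2 difference between the named replicates on the vertical axis; dashed lines mark a difference of 1 in either direction. The pair of replicates 1 and 3 has 4 genes at or beyond the lines, and the pairs with replicate 2 have 52 and 73.

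By limma's variance test, 2 genes passed at a Benjamini-Hochberg adjusted p under 0.05. The 3 unchanged genes that passed on simulated arrays are no yardstick for this count. Those arrays also held genes raised 2-fold and 4-fold, which loosens the adjustment. An unadjusted p under 0.05 was found for 932 genes, where 811 would be expected by chance under limma's fitted prior. The prior was fitted to these same genes, so the chance counts given here and below are no independent expectation. The first had log2 intensities of 5.79, 6.94 and 5.76 in replicates 1, 2 and 3, with an adjusted p of 0.001 by limma. The second had 5.83, 5.90 and 6.58, with an adjusted p of 0.036 by limma. In each, the lower samples were close to 5.86, the mean of the lowest quartile of genes. With the negative control threshold 0 genes passed limma's adjusted test and 762 had an unadjusted p under 0.05, and after subtracting block medians these counts were 0 and 827, where chance gives 653 and 811 unadjusted. The adjusted count went the other way in other settings, to 25 with median scaling, 31 without the filter on dim probes, 11 with local background, and 10, 40 and 11 without replicates 1, 2 and 3. Unadjusted counts in these settings lay on both sides of chance. They were 675 with median scaling, 937 with local background, and 919, 771 and 878 without replicates 1, 2 and 3, each against 811. Without the filter the unadjusted count was 1141 against 1008. In the 8113 genes at or above the median level, 9 passed limma's adjusted test and 578 had an unadjusted p under 0.05, against 406.

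Differences between arrays also followed position. The array is printed in 24 blocks, and the median difference of replicate 1 from the mean of the other arrays ran from -0.097 in block 3 to 0.067 in block 21 on the log2 scale, with a standard error of a block median of at most 0.008. Replicate 3 ran from 0.057 in block 4 to -0.046 in block 17 (standard error at most 0.0097), and replicate 2 from 0.040 in block 1 to -0.025 in block 20 (at most 0.013). These standard errors come from the spread over the genes of a block, treated as independent. They do not measure the spread between samples. The span over blocks was 0.16, 0.065 and 0.10 for replicates 1, 2 and 3. For each gene these differences cancel over the arrays, so the trends are not independent. A gradient in a single array would give opposite trends in the others.

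**Figure D3:**
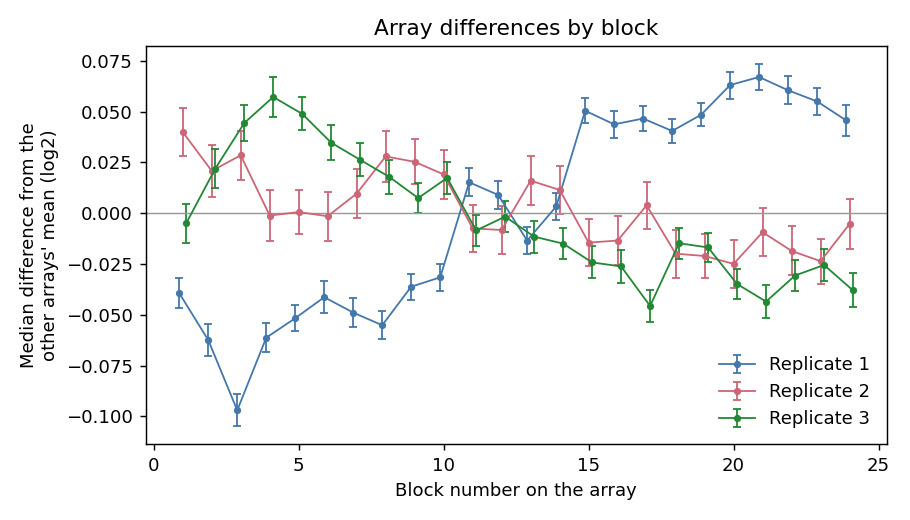
Points give the median log2 difference of each replicate from the mean of the other arrays (vertical axis) over the gene probes of each block (horizontal axis). Bars give the standard error of the median over the genes of the block, treated as independent. Replicate 1 rises from -0.097 in block 3 to 0.067 in block 21 while replicate 3 falls from 0.057 in block 4 to -0.046 in block 17. The differences of a gene cancel over the arrays, so these trends are not independent.

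The local background reported beside each spot followed the spot intensity on all 3 arrays, to different degrees. For gene spots brighter than 500 units, the local background was a median 73.6% of the spot intensity in replicate 1, 22.0% in replicate 2 and 44.3% in replicate 3. Beside blank spots its median was 50.5, 51.1 and 58.8 units. On the log scale, local background changed with spot intensity with a slope of 0.96 in replicate 1, 0.79 in replicate 2 and 0.92 in replicate 3 among those bright spots.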

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

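The test of the relabelled positions was chosen after the result was seen. Spots outside the gene probes carried signal above the blank threshold. Among spots labelled no probe, 43.7% passed in replicate 1, 41.0% in replicate 2 and 32.1% in replicate 3. Among negative control spots, 76.0% passed in replicate 1, 89.6% in replicate 2 and 52.1% in replicate 3.

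In replicates 1 and 3 the blank spots all lie in row 11 of their blocks, but that place alone does not account for the empty spots that passed there: in that same row, 49.0% of the spots labelled no probe passed in replicate 1 and 33.9% in replicate 3. In replicate 2 the signal went with the label in part. At 4464 positions that replicates 1 and 3 label no probe, replicate 2 labels the spot blank, and there 13.9% exceeded the threshold of the 1344 positions blank on all arrays, against 53.8% of the 809 positions labelled no probe on all arrays and 5.06% of the always-blank positions, which set that threshold. Spots that share the blank label thus also differed by position. A candidate explanation is that spots labelled no probe and blank were prepared differently, which would account for part of the pattern. Light from bright neighbours stays open, since the Spearman correlation of a no probe spot with its brightest neighbour was 0.27, 0.087 and 0.17 in replicates 1, 2 and 3. The design has no second group, so no biological explanation was tested.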

How the results depend on the processing

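The count of gene probes above background on all arrays (16226) stayed between 13058 and 17330 under 9 of 10 alternatives, including 15472 at 3 SD and 14750 with the no probe threshold, and fell to 3612 with the threshold from local background values; leaving out an array gave 16335 to 16858. The count of genes with a 2-fold range (101) was 186 with median scaling and 1475 with the blank mean subtracted. It was 2647 in the value table, 2075 with local background, and 4 to 73 leaving out an array. Of the 101 genes, 100 or 101 were shared under either filter on dim probes and with no filter. Filters leave the values unchanged, so this overlap only counts the genes kept and does not test the result. Shared genes numbered 98 with cyclic loess, 98 with the blank mean subtracted, 93 with block medians subtracted and 75 with median scaling. They numbered 68 in the value table and 65 with local background. Without replicates 1, 2 and 3 in turn, 73, 4 and 52 were shared. These are all the genes 2-fold apart in the remaining pair, since any such gene has a 2-fold range over 3 arrays. That overlap is therefore fixed in advance. The number passing limma's variance test (2) was 25 with median scaling, 1 with the blank mean subtracted, 31 without the filter and 1 with cyclic loess. It was 0 with block medians subtracted, 0 with the negative control threshold, 11 with local background and 10 to 40 leaving out an array. In the value table it was 3, and among genes at or above the median level it was 9. The median Pearson r (0.989) was 0.920 with local background and 0.988 to 0.996 leaving out an array. The median SD (0.093) was 0.11 with median scaling, 0.24 with the blank mean subtracted, 0.064 without the filter, 0.30 in the value table, 0.15 with local background, 0.12 with the negative control threshold, and 0.051 to 0.081 leaving out an array. Counts without an array compare 2 arrays in place of 3; the cause of the other changes was not tested, except that the offset of 50 shrinks differences of dim probes by construction. No paired analysis was possible because the samples form a single group. Alternatives for the gene lists were not run, since no probe identifier could be matched to a symbol. Probes within a few units of the blank mean are limited by signal over background.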

Other observations

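The tests of dim probes and of the array printing were chosen after the result was seen. The block median and cyclic loess settings were also not among those planned before the data were examined. Replicate 2 stood farthest from the middle array for 87.1% of the genes with a 2-fold range and for 48.4% of all 16226 genes, and it also differs in layout: 4464 positions labelled no probe on replicates 1 and 3 are labelled blank on it. A gradient between blocks is argued against as the whole cause, since block medians spanned only 0.16, 0.065 and 0.10 on the log2 scale in replicates 1, 2 and 3. Subtracting them left replicate 2 farthest for 90.3% of such genes, a share that shifts this small could hardly change. Position within a block was not tested. Cyclic loess in place of quantile normalization gave 88.6%. Quantile normalization already evens out intensity distributions between arrays, so this swap cannot decide on an intensity-dependent curve. Noise of dim probes is argued against by 83.7% among the 8113 genes above the median level with the blank mean subtracted and no offset, where 300 had a 2-fold range. With normexp on the local background 2075 genes had a 2-fold range, and replicate 2 was farthest for 530 of them (25.5%), replicate 1 for 1045 (50.4%) and replicate 3 for 500. Another printing of the array, a technical difference in RNA handling or hybridization and a difference between the cells cannot be told apart, because only 1 array has replicate 2's layout and the samples share all other labels.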
